A study of Arabidopsis thaliana with 8 samples.

How the data were processed

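The series holds 8 RNA-seq libraries of whole Arabidopsis seedlings: 3 of wild type Col-0, 2 of RNAi line 5 and 3 of RNAi line 12, grouped by their titles. Seedlings were kept for 3 days at 4 °C and grown for 7 days at 22 °C on MS plates with 16 h of light and 8 h of dark, and 1.5 µg of total RNA went into each TruSeq RNA library, per the labels' protocols. HISAT2 and StringTie, with no versions, and the build TAIR10 are named per the submitters' processing notes. The counting step, the annotation version and the strand setting are not given in the sources used here, so overlapping and antisense genes may share reads.

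The authors deposited 1 table of 32833 genes with 1 FPKM column per library; no header names the unit, and FPKM was inferred from the values. The columns summed to 590189 to 630761, which excludes TPM and CPM. Low values times gene length fell on whole multiples of 1 step per library for 85.79% to 87.23% of values (tolerance 0.01 reads), which implied 42280000 to 49010000 fragments per library. Read counts were not recovered from them. All 8 value columns were mapped to samples. Of the gene IDs, 32548 were in the reference table, 32532 of them with the same start and end.

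A count-based test fixed beforehand was replaced by the branch fixed for FPKM, since no counts were analysed. Genes with at least 1 FPKM in at least 2 libraries (19395) were tested with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with an intensity trend, in 1 fit of 3 groups over 8 libraries (prior degrees of freedom 2.711). Contrasts were line 5 less WT, line 12 less WT, the mean of both lines less WT, and line 12 less line 5, with Benjamini-Hochberg adjustment and a threshold of 0.05. ABCE2 was also compared by exact permutation tests (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9). The procedure was tested on simulated data with 200 changed genes among 19395: a log2 change of 1 was recovered in 77.6% of cases for line 5, 89.6% for line 12 and 89.6% for the mean of the lines, a change of 0.5 in 37.3%, 41.8% and 55.2%, and a change of 2 in 98.5% for each. The false share of calls was 3.4%, 3.77% and 3.57%. Far fewer genes changed there than were called against WT in the measured data (44.6% to 56.1%). The simulated genes also varied independently, with the same spread in every group. The recovered and false shares therefore hold for that setting and may differ in the measured data.

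In all, 32 gene lists were fixed before the data were examined, as were the tests, the filters and the alternatives, except those said below to be added. Of 575 members written, 564 matched by locus and symbol and 2 by symbol alone, 5 were dropped and 4 named a gene already in the list, while a rule on descriptions (ribosomal proteins) added 386. Lists were tested with camera (limma) at a preset correlation of 0.01 and with an estimated correlation, adjusted over all lists and contrasts. In simulated data the 1 shifted list was called and 0 of 30 unshifted ones. The simulated genes varied independently of each other, while the estimated correlation within measured lists reached 0.763 (root markers). The simulation therefore does not show how often camera calls unshifted lists of correlated genes. The lists cover rapid stress and touch, jasmonate, ethylene, salicylic acid, abscisic acid, mitochondrial and oxidative stress, DNA damage, heat shock and unfolded proteins. They also cover flavonoids, glucosinolates, phosphate, iron, nitrate, photosynthesis, the clock, cell cycle, cell wall, auxin (synthesis and response), leaf polarity, root, guard cell, vascular, trichome and seed storage genes. The remaining lists are cytosolic and plastid ribosomal proteins, ribosome biogenesis, translation factors, ribosome rescue and RNA silencing.

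Genes named in the text followed a rule fixed beforehand. It took ABCE2 and its relatives; the 8 highest and 8 lowest genes called in both lines, by the smaller fold, with every RNAi library beyond every WT library; and the 5 highest and 5 lowest called genes of each line and of their difference, all above the median level of tested genes. It also took up to 4 called members of each list with the largest change in the mean of the lines, or the 2 most abundant where fewer than 2 were called. Genes without a symbol are named by locus, and some genes that the rule took are not reported here.

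Alternatives were median centring, no filter, a filter at 5 FPKM, a pseudocount of 0.1, the replicate number as a block, fits on fewer groups, a 2-fold minimum and leaving out each library. After the data were seen, 3 more were added: leaving out the 3 libraries above 2% ribosomal RNA, rescaling without ribosomal RNA and organelle genes, and Fisher's exact tests of the table's own GO and KEGG terms (10 to 500 genes). The sets of morning and evening clock genes were also chosen then.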

Results

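Transcript levels were measured by RNA sequencing in whole Arabidopsis seedlings, in 8 libraries that fell into 3 groups. Wild type (WT, Col-0) had 3 libraries, RNAi line 5 had 2 and RNAi line 12 had 3. Both lines carry an RNA interference construct against RLI2, listed as ABCE2 in the table, an ATPase of the family that splits ribosomes into subunits after translation ends. The values implied 42280000 to 49010000 fragments per library, and 18218 to 18565 genes reached 1 FPKM (fragment counts scaled by gene length and depth). Levels below are mean FPKM ± SD over 3 WT, 2 line 5 and 3 line 12 libraries, and fold changes are log2 differences of FPKM + 1, which understate the change of low genes. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. For the mean of both lines this is the spread within groups, so those p-values do not measure how far the lines agree. Fragments from ribosomal RNA genes made up 0.192% to 0.412% of each WT library. That share was 0.468% and 2.175% in line 5, and 0.161%, 2.338% and 7.602% in line 12.

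The target transcript was lower in every RNAi library than in every WT library. ABCE2 (AT4G19210, TAIR10 chromosome 4, 10501123 to 10505217, 13 exons of which 11 are coding) stood at 58.0 ± 0.541 FPKM in WT, 25.7 ± 0.998 in line 5 and 25.5 ± 1.87 in line 12. This left 44.3% of the WT level in line 5 and 44.0% in line 12. The fold change was -1.14 (SE 0.069, limma adjusted p = 1.77e-05) in line 5 and -1.16 (SE 0.062, adjusted p = 6.98e-06) in line 12. The lines differed from each other by -0.01 (SE 0.069, adjusted p = 0.919), with a 95% interval from -0.17 to 0.15. An exact two-sided permutation test of the 5 RNAi libraries against the 3 WT libraries gave p = 0.0179, the smallest that 56 splits allow. For line 12 alone, the exact permutation p was 0.1, the smallest that 3 against 3 allows. The relatives ABCE1 (0.353 ± 0.0135 FPKM in WT, 0.253 ± 0.104 in line 5, 0.311 ± 0.109 in line 12) and ABCE3 (at most 0.173 FPKM in any library) lay below the filter and were not tested. Reads from the RNAi construct itself would count toward ABCE2 if the construct was transcribed, and could not be separated here.

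**Figure D1:**
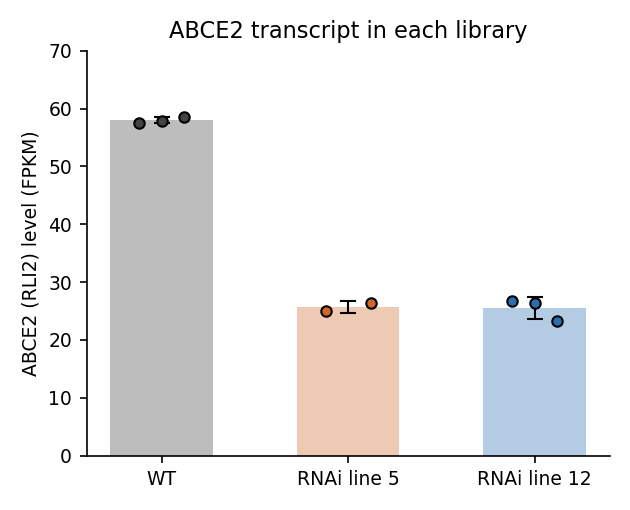
ABCE2 level in FPKM (vertical axis) for WT, RNAi line 5 and RNAi line 12. Bars are group means, error bars are SD and points are the 3, 2 and 3 libraries, with every RNAi library between 23.3 and 26.7 FPKM and every WT library above 57.5.

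The comparison of line 5 with WT asked which transcripts differ in the first of the knockdown lines. CBF2, a transcription factor of the cold response, rose from 0.486 ± 0.359 FPKM to 55.7 ± 6.59 (log2 5.28, SE 0.202, adjusted p = 2.88e-06). AT1G07135 rose from 2.70 ± 0.843 to 128.2 ± 15.8 FPKM, and FBS1, an F-box protein induced by stress, from 1.91 ± 0.320 to 90.8 ± 6.63. AT1G05675 rose by 4.90 and DIC2, a mitochondrial dicarboxylate carrier, by 4.74 on the log2 scale. ELIP2 and ELIP1, early light-induced proteins of the chloroplast, changed by -3.61 and -3.09, TT4 (chalcone synthase) by -3.33 and ATSDI1, a gene of the response to low sulfur, by -3.34. AT5G37990 changed by -3.05 (adjusted p = 0.0085), and by -2.12 (adjusted p = 0.0686) without line 5 replicate 1. In all, 8645 of 19395 tested genes passed, 4311 higher and 4334 lower, and 1835 of them changed at least 2-fold (1101 higher, 734 lower). The share of calls that were higher was 49.9%, against 43.2% after median centring and 52.4% after rescaling without ribosomal RNA and organelle genes. Without line 5 replicate 1 the count was 5455, with the single remaining line 5 library assumed to vary like the other groups. Without the 3 libraries above 2% ribosomal RNA, an alternative added after the data were seen, it was 6659. That fit holds 1 library of each line wherever it is given, so its spread comes from the 3 WT libraries alone. Camera called 14 of 32 lists, and 0 with an estimated correlation. With a filter at 5 FPKM it called 9 of 31. The DNA damage list (median 0.57, adjusted p = 0.0468) lost its call without WT replicate 1 (adjusted p = 0.061), WT replicate 2 (0.0574) or line 5 replicate 1 (0.0823).

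The comparison of line 12 with WT asked the same of the other line. AT4G12735 rose from 0.790 ± 0.145 to 79.3 ± 27.1 FPKM (log2 5.42, SE 0.333, adjusted p = 1.2e-05). AT2G04050 and AT2G04070, transporters of the MATE efflux family that resemble each other and may share reads, rose by 5.25 and 5.10, AT2G18193 by 4.86 and AT5G13210 by 4.74. ELIP2 changed by -4.32, from 187.5 ± 7.87 to 8.46 ± 0.683 FPKM. MS2, a methionine synthase, went from 295.8 ± 9.44 to 31.2 ± 1.37 FPKM (log2 -3.21, SE 0.061, adjusted p = 4.16e-07), and THI2.2, a thionin, changed by -3.59. TT4 changed by -3.20 and AT5G38020 by -3.11. A total of 10856 of 19395 genes passed, 5486 higher and 5370 lower, with 2152 changed at least 2-fold (1262 higher, 890 lower). Without the 3 libraries above 2% ribosomal RNA, which leaves 1 library of line 12, the count was 7012. Camera called 19 of 32 lists, and 0 with an estimated correlation.

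Many of the same genes passed in both lines with the same direction. Among genes above the median level, those with the largest smaller fold of the pair included AT4G12735, DIC2, BCB (a blue copper protein), CYP81D8 (a cytochrome P450), CBF2, NAC044 (a transcription factor of the DNA damage response) and AT5G52750. BCB rose from 13.2 ± 5.24 to 215.5 ± 15.5 FPKM in line 5 and 216.6 ± 49.4 in line 12. CYP81D8 rose by 4.00 and 3.96, NAC044 by 3.74 and 4.06, and AT5G52750 by 3.87 and 3.73 on the log2 scale. On the lower side stood CHIL, a chalcone isomerase-like protein (-2.80 in line 5 and -3.10 in line 12), AT1G06000 (-2.72 and -3.08), FLS1, a flavonol synthase (-2.60 and -2.83), and THAS1, thalianol synthase (-2.55 and -2.64). In number, 3419 genes were higher and 3439 lower in both lines, 6858 in all, against 150 that passed in opposite directions. Independent lists of these sizes would share 1219.4 higher and 1200 lower genes. In 100 simulations of unchanged lines against the same WT libraries there were 0 shared calls. No gene was changed in either simulated line, so few calls could arise, and this count is no baseline for the overlap. Across genes, which are not independent replicates, the fold changes correlated with r = 0.824 (simulated 0.446) and a covariance of 0.381 (simulated 0.0125, difference 0.369), and 81.8% had the same sign (simulated 64.7%). The simulated covariance of 0.0125 carries the spread between the shared WT libraries, which argues against that spread as the main source of the covariance. A difference common to all 3 WT libraries would add to both lines and was not tested, so part of the excess may come from it. Without the 3 libraries above 2% ribosomal RNA, 4809 genes passed in both lines.

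**Figure D2:**
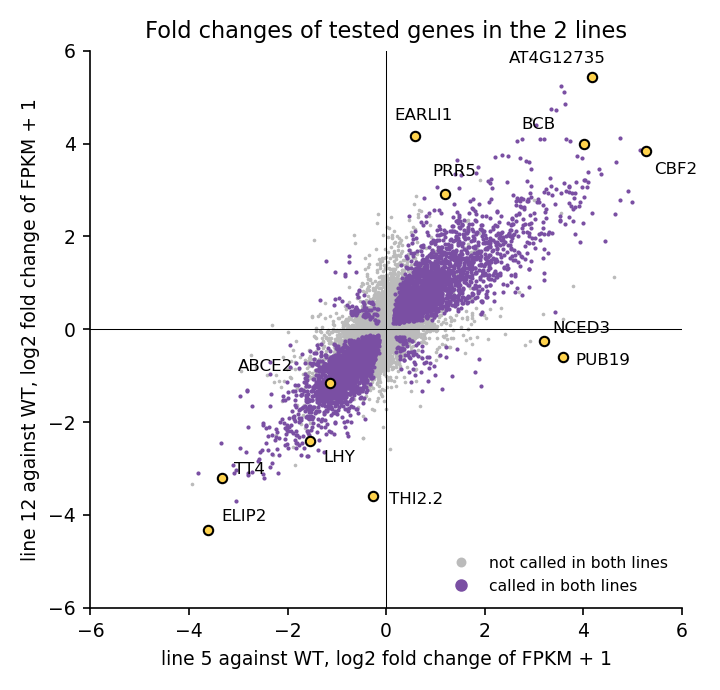
Log2 fold change of FPKM + 1 against WT in line 5 (horizontal axis) and line 12 (vertical axis), 1 point per tested gene, with 12 named genes marked. Purple points passed the test in both lines. Across all tested genes, purple or not, the fold changes correlated with r = 0.824. EARLI1, THI2.2, PUB19 and NCED3 lie off the diagonal, and of these only PUB19 passed in both lines.

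The mean of both lines against WT, the comparison the series is built on, was led by the rapid stress transcription factors and touch genes, of which all 18 measured members rose (18 adjusted over the list alone, median log2 change 3.26). CBF2 rose by 4.56 (SE 0.163) and its relative CBF1, at 0.0130 ± 0.0224 FPKM in WT, reached 26.3 ± 0.950 in line 5 and 6.08 ± 1.69 in line 12. STZ (ZAT10), a zinc finger repressor, rose by 3.89 (SE 0.234), and SZF1, a salt-inducible zinc finger protein, from 8.40 ± 1.75 to 157.5 ± 14.4 and 96.6 ± 2.83 FPKM. The list was called by camera (adjusted p = 7.23e-12, and adjusted p = 0.546 with an estimated correlation). Of all tested genes, 56.1% passed in the mean of the lines, 5443 higher and 5441 lower. The share was 44.6% in line 5, 56% in line 12 and 19% between the lines. Member counts of lists are to be read against these shares, since several lists lie near them. Of 20 measured jasmonate genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone, median 1.07, camera adjusted p = 0.000204, and adjusted p = 0.546 with an estimated correlation). LOX4 and LOX3, lipoxygenases of jasmonate synthesis, rose by 2.93 and 2.09 and the repressor JAZ1 by 1.91, while TAT3, a tyrosine aminotransferase, changed by -2.30. Genes annotated to the response to jasmonic acid were enriched in both directions (Fisher's exact test, chosen after the data were seen). They were 15 of 133 among genes at least 2-fold higher in both lines (5.02 expected, adjusted p = 0.00497) and 14 among those at least 2-fold lower (3.75 expected, adjusted p = 0.00266). Ethylene genes had 9 of 18 members higher and 1 lower (9 and 2 adjusted over the list alone, median 0.31, camera adjusted p = 0.0272, and adjusted p = 0.57 with an estimated correlation), led by ERF104 (2.49), ACS6 (1.91), ACS8 (1.43) and ERF2 (1.39), of which the ACS genes encode enzymes of ethylene synthesis. The ethylene list was called in line 12 (13 of 18 higher, 1 lower, 13 and 1 adjusted over the list alone, median 0.82, camera adjusted p = 0.00127, and adjusted p = 0.546 with an estimated correlation) and not in line 5 (5 higher, 5 lower, median -0.06, camera adjusted p = 0.884). Of its leading members, ERF104, ACS6 and ACS8 rose by 2.89, 2.61 and 1.75 in line 5 and by 2.08, 1.2 and 1.105 in line 12. The clock genes moved with these groups: LHY and CCA1 were lower and TOC1 and PRR5 higher in both lines, as given further on.

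Genes of mitochondrial dysfunction and of DNA damage were mostly higher in the mean of the lines. In the mitochondrial and oxidative stress list 11 of 16 members rose and 1 fell (11 and 1 adjusted over the list alone, median 1.17, camera adjusted p = 0.000634, and adjusted p = 0.552 with an estimated correlation). AOX1A, the alternative oxidase, rose from 24.6 ± 1.36 to 71.0 ± 20.7 FPKM in line 5 and 131.1 ± 28.0 in line 12, BCS1 by 3.26, UGT74E2 by 2.38 and NDB4 by 1.88 on the log2 scale. In the DNA damage list 8 of 13 members rose and 1 fell (8 and 1 adjusted over the list alone, median 0.77, camera adjusted p = 0.0223, and adjusted p = 0.619 with an estimated correlation). NAC044 rose by 3.90 and GMI1 by 1.94, and AT3G27630 (SMR7) and AT1G07500 (SMR5), inhibitors of the cell cycle, by 1.32 and 1.11. By line, 9 and 12 of the 16 mitochondrial members and 7 and 9 of the 13 DNA damage members were higher in line 5 and line 12. The DNA damage call in the mean ended with a filter at 5 FPKM (adjusted p = 0.0777). That filter also ended the calls in line 5 (adjusted p = 0.0756) and line 12 (0.0807), and rescaling ended that in line 5 (0.0503).

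Flavonoid and glucosinolate synthesis genes were lower almost throughout. Of 15 measured flavonoid genes 13 fell and 0 rose (13 and 0 adjusted over the list alone, median -1.44, camera adjusted p = 4.86e-06, and adjusted p = 0.57 with an estimated correlation). TT4 fell from 254.7 ± 31.3 FPKM to 24.4 ± 4.24 in line 5 and 26.8 ± 2.91 in line 12, and F3H, flavanone 3-hydroxylase, from 63.6 ± 8.24 to 11.6 ± 1.52 and 7.24 ± 0.532. FLS1 changed by -2.72 and 4CL3, a 4-coumarate:CoA ligase, by -2.56. All 18 measured glucosinolate genes fell (18 adjusted over the list alone, median -1.28, camera adjusted p = 2.47e-08, and adjusted p = 0.546 with an estimated correlation), among them BCAT4, which starts methionine chain elongation (-2.24, SE 0.155), the cytochrome P450 genes CYP79F2 (-2.02) and CYP79F1 (-1.99), near-identical neighbours whose reads may be shared, and CYP83A1 (-1.99). The same libraries had less LHY and CCA1 and more TOC1 and PRR5.

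**Figure D3:**
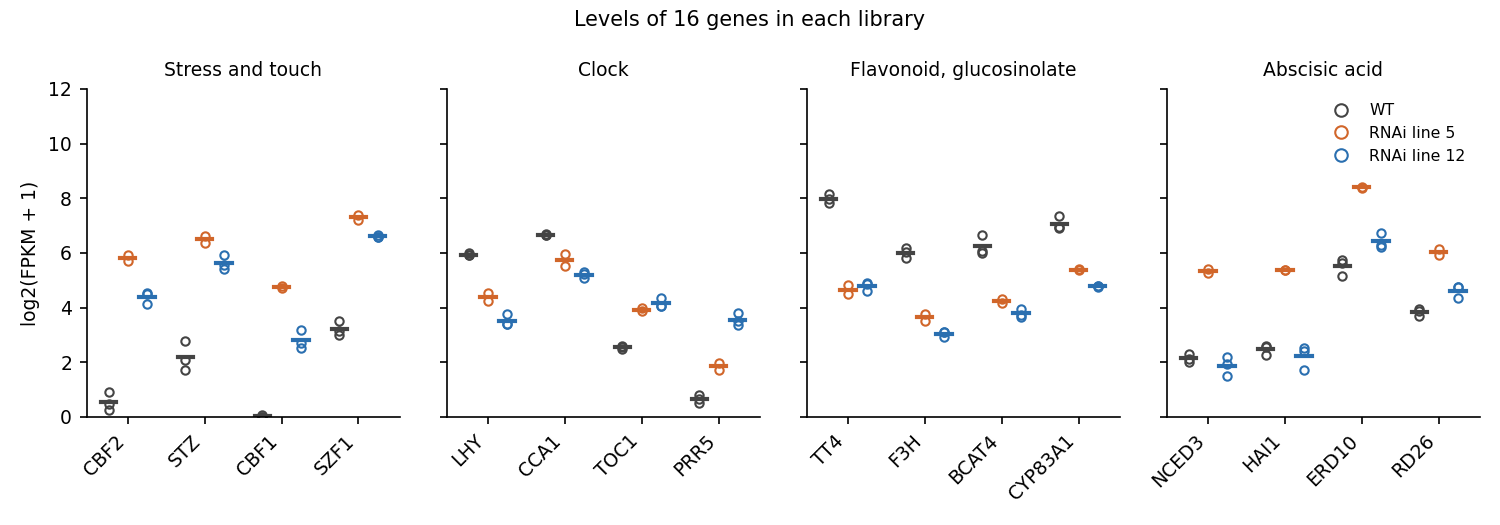
Level of 16 genes as log2(FPKM + 1) on the vertical axis, in 4 groups, with open circles for the 8 libraries and short lines for the mean of WT, line 5 and line 12. CBF2, STZ, CBF1 and SZF1 were higher and TT4, F3H, BCAT4 and CYP83A1 lower in both lines, while NCED3 and HAI1 were higher in line 5 and at 2.75 and 3.76 FPKM in line 12, against 3.42 and 4.55 in WT.

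Clock genes changed in both lines, in both directions. LHY and CCA1, transcription factors that peak around dawn, fell from 60.1 ± 1.78 to 20.2 ± 2.93 and 10.6 ± 1.8 FPKM and from 101.1 ± 2.22 to 53.3 ± 12.0 and 35.9 ± 2.51, in line 5 and line 12. TOC1 and PRR5, which peak later in the day, rose from 4.82 ± 0.242 to 14.2 ± 0.619 and 16.9 ± 2.17 and from 0.578 ± 0.160 to 2.62 ± 0.455 and 10.9 ± 1.85. Of 13 measured clock genes 6 rose and 5 fell (6 and 5 adjusted over the list alone, median 0.20), so the list as a whole was not called (camera adjusted p = 0.534). The difference between lines was -0.88 for LHY (SE 0.131, adjusted p = 0.0042) and 1.71 for PRR5 (SE 0.155, adjusted p = 0.000696). The hour of harvest is not given in the sources used here.

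Genes of nutrient status moved in several directions, in libraries where the root marker list, given further on, was lower (median -1.06, 9 of 14 lower). Of 12 phosphate starvation genes 8 fell and 0 rose (8 and 0 adjusted over the list alone, median -1.34, camera adjusted p = 0.0062, and adjusted p = 0.69 with an estimated correlation), including SQD1 and SQD2 of sulfolipid synthesis (-1.70 and -1.47) and the noncoding RNA IPS1 (-1.92). MGDC (MGD3), a galactolipid synthase, changed by -1.88 (adjusted p = 0.0143), and this call ended without WT replicate 1 (-1.46, adjusted p = 0.0573) or WT replicate 2 (-1.70, adjusted p = 0.0557). In the iron list 4 of 13 members rose and 7 fell (4 and 7 adjusted over the list alone), without a call (camera adjusted p = 0.417). NAS4, a nicotianamine synthase, changed by -2.44, and the iron-deficiency regulators BHLH100 and BHLH101 by -1.81 and -1.44, while bHLH39, at 1.64 ± 0.50 FPKM in WT, was listed at 0 in both line 5 libraries. Nitrate genes had 8 of 13 members higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.0554). At the preset correlation the list passed without WT replicate 3 (camera adjusted p = 0.0476) or line 12 replicate 1 (0.034), with no filter (0.0364) and after median centring (0.0486). With an estimated correlation and all libraries, the adjusted p was 0.546. ASN1, an asparagine synthetase, rose from 46.5 ± 9.74 to 446.4 ± 73.1 and 385.1 ± 72.1 FPKM, and the glutamate dehydrogenases GDH1 and GDH2 rose by 2.03 and 1.15 and the nitrate reductase NIA1 by 0.89.

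Chaperones of the endoplasmic reticulum and the cytosol were mostly lower. In the unfolded protein list 10 of 14 members fell and 3 rose (10 and 3 adjusted over the list alone, median -0.64, camera adjusted p = 0.0143, and adjusted p = 0.57 with an estimated correlation). BIP2, a luminal HSP70, fell from 98.7 ± 5.01 FPKM to 52.0 ± 0.586 and 46.1 ± 3.36, and PDIL2-2, a disulfide isomerase, changed by -0.94, whereas the regulators BZIP60 and NAC103 rose by 1.61 and 1.09. In the heat shock list 10 of 16 members fell and 3 rose (10 and 3 adjusted over the list alone, median -0.67, camera adjusted p = 0.0165, and adjusted p = 0.57 with an estimated correlation). HSP70 (AT3G12580) fell from 53.8 ± 2.96 to 11.1 ± 2.82 and 8.26 ± 1.53 FPKM, and HSP17.4, HSP17.6II and AT5G48570 changed by -2.27, -2.19 and -1.67. The heat shock call ended with a filter at 5 FPKM (adjusted p = 0.0736).

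Genes of dividing and differentiating cells were mostly lower. Cell cycle genes had 12 of 21 members lower and 2 higher (12 and 2 adjusted over the list alone, median -0.39, camera adjusted p = 0.0093, and adjusted p = 0.546 with an estimated correlation), with PCNA1 at -0.89, PRL (MCM7) at -0.77 and CDT1A at -0.76, all of DNA replication, and CYCB1;1, a mitotic cyclin, higher by 1.41. All but 1 of 11 guard cell and stomatal lineage markers fell (10 adjusted over the list alone, median -0.70, camera adjusted p = 0.000518, and adjusted p = 0.546 with an estimated correlation), with EPF2 at -1.20, TMM at -1.09, MYB60 at -0.93 and SPCH at -0.90. Leaf polarity and meristem genes had 10 of 19 members lower and 1 higher (10 and 1 adjusted over the list alone, median -0.33, camera adjusted p = 0.0195, and adjusted p = 0.546 with an estimated correlation), with ARF4 at -0.93, KAN2 at -0.78, KAN3 at -0.76 and CUC3 at -0.72. Of 14 root markers 9 fell and 0 rose (10 adjusted over the list alone, median -1.06, camera adjusted p = 0.0082, and adjusted p = 0.704 with an estimated correlation). PRP3 changed by -1.61, CASP1 by -1.17, LRX1 by -1.16 and CASP4 of the endodermal barrier by -1.07. In line 12, 5 of 14 root markers were lower (3 adjusted over the list alone). PRP3, CASP1 and LRX1 did not pass in line 12 (limma adjusted p = 0.21, 0.104 and 0.138). With a filter at 5 FPKM the root and guard cell calls in the mean of the lines ended (camera adjusted p = 0.134 and 0.05). In line 12 alone the root call ended with that filter (adjusted p = 0.236), without WT replicate 2 (0.0736) and without the 3 libraries above 2% ribosomal RNA (0.0976). It also ended without line 12 replicate 2 (adjusted p = 0.0903), with the median at -0.33 in place of -0.79. The root list was not called between the lines (0.27, camera adjusted p = 0.23, and adjusted p = 0.875 with an estimated correlation). At the preset correlation it was higher in line 12 without line 12 replicate 2 (0.53, camera adjusted p = 0.000791). The difference was 0.60 without line 5 replicate 2 and 1.05 without the 3 libraries above 2% ribosomal RNA, fits that leave 1 line 5 library.

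Other lists of growth and of cell types were not called in the mean of the lines with all libraries and the filter at 1 FPKM. Vascular genes had 8 of 11 members lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.0504), with IRX1 at -0.54 and XCP2 at -0.48. The vascular list passed in 7 alternatives, among them without WT replicate 3 (adjusted p = 0.0244), line 12 replicate 1 (0.0275) or line 12 replicate 3 (0.0373). It was called in line 12 (9 of 11 lower, 1 higher, 9 and 1 adjusted over the list alone, camera adjusted p = 0.0218, and adjusted p = 0.643 with an estimated correlation), a call that ended with a filter at 5 FPKM (adjusted p = 0.11). Trichome genes had 4 of 7 lower and 0 higher (4 adjusted over the list alone, camera adjusted p = 0.122), with GIS at -0.82 and TRY at -0.63. Auxin synthesis and transport genes had 2 of 17 higher and 8 lower (2 and 8 adjusted over the list alone, camera adjusted p = 0.184), with LAX3 at -0.72, TAR2 at -0.69 and YUC9 higher by 1.32. Early auxin genes had 2 of 23 higher and 9 lower (2 and 9 adjusted over the list alone, camera adjusted p = 0.122), with SAUR15 at -1.23 and IAA5 at -0.90. They were called in line 12 (2 higher, 12 lower, 2 and 12 adjusted over the list alone, camera adjusted p = 0.00876, and adjusted p = 0.69 with an estimated correlation). In the cell wall list 4 of 16 rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.256), and its median (-0.38) and mean (0.17) differed in sign. The members that rose were the xyloglucan-modifying enzymes TCH4 (13.3 ± 4.84 FPKM in WT, 105.5 ± 7.36 in line 5 and 151.7 ± 14.5 in line 12), XTH18 (2.80), XTH24 (2.28) and XTH19 (1.42). Salicylic acid genes had 6 of 18 higher and 8 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.796), with CBP60G and SAG101 higher by 1.90 and 1.54, ACD6 at -2.28 and PR1 at -2.50. Of the seed storage list 4 of 13 members were tested and 1 rose, ABI5 by 0.90 (1 adjusted over the list alone, camera adjusted p = 0.976), while CRA1 ranged around 5.65 ± 8.95 FPKM in WT.

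Transcripts of the translation machinery shifted little. In the broad list of cytosolic ribosomal proteins, 34 of 309 measured members rose and 110 fell (32 and 109 adjusted over the list alone, median -0.12, camera adjusted p = 0.0158, and adjusted p = 0.875 with an estimated correlation). Its call ended without WT replicate 3 (adjusted p = 0.0906) or line 5 replicate 2 (adjusted p = 0.081). Among its largest changes, AT5G16200 (1.16), AT5G15260 (0.97) and AT1G14205 (0.93) are genes taken in by the wording of their descriptions. Ribosome biogenesis genes had 3 of 18 higher and 6 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.256), with NUC-L2, a nucleolin, higher by 1.14 and FIB1, a fibrillarin, at -0.50. Translation factors had 3 of 20 higher and 5 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.471), with the kinase S6K2 higher by 1.52, ATARCA (RACK1A) at -0.64 and EIF4E at -0.44. Among ribosome rescue and mRNA surveillance genes 8 of 25 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.417). ERF1-1, a release factor, rose from 34.0 ± 0.0395 to 59.5 ± 14.4 and 88.2 ± 13.8 FPKM, and PEL1, a Pelota homologue, by 0.27, a change that missed the threshold without the 3 libraries above 2% ribosomal RNA (adjusted p = 0.0507). RNA silencing genes had 6 of 23 higher and 6 lower (6 and 6 adjusted over the list alone, camera adjusted p = 0.797, median -0.08 and mean 0.003, which differ in sign), with AGO3 higher by 1.07 and DCL1 at -0.44.

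Chloroplast genes were lower as lists in line 12 and were not called in the mean of the lines. Photosynthesis genes had 4 of 28 higher and 12 lower (4 and 12 adjusted over the list alone, median -0.13, camera adjusted p = 0.231). In line 5 the numbers were 10 and 8 (camera adjusted p = 0.747). In line 12 they were 2 and 16 (2 and 16 adjusted over the list alone, median -0.29, camera adjusted p = 0.00762, and adjusted p = 0.723 with an estimated correlation), a call lost without the 3 libraries above 2% ribosomal RNA (adjusted p = 0.075). PORB, of chlorophyll synthesis, rose from 62.4 ± 2.95 to 207.3 ± 15.3 and 236.8 ± 31.2 FPKM and GAPB of the Calvin cycle changed by -0.63. LHB1B1 (1.23) and RBCS2B (-0.51) have near-identical copies, which makes their values uncertain. Plastid ribosomal proteins had 0 of 72 higher and 11 lower (10 adjusted over the list alone, median -0.04 and mean 0.002, which differ in sign, camera adjusted p = 0.266), such as EMB3136 (-0.40). In line 12 there were 1 higher and 21 lower (0 and 20 adjusted over the list alone, median -0.14, camera adjusted p = 0.0219, and adjusted p = 0.752 with an estimated correlation). The mean of the lines passed after rescaling (camera adjusted p = 0.045), which left out organelle genes and so also any plastid-encoded members of the list. Before rescaling, the adjusted p with an estimated correlation was 0.877. Over all genes, the mean of the lines gave 10884 calls among 19395, 5443 higher and 5441 lower, with 1851 changed at least 2-fold (1086 higher, 765 lower), and 8833 calls without the 3 libraries above 2% ribosomal RNA. Some genes passed in the mean though the lines disagreed. PUB19 did so at 1.50 (limma adjusted p = 0.000123), with line 12 at -0.59 (adjusted p = 0.0196). NCED3 did so at 1.47 (adjusted p = 0.000148), with line 12 at -0.26 (adjusted p = 0.232). The share of calls that were higher was 50.0% in the mean with all libraries, 43.6% after median centring and 54.0% after rescaling. Of 32 lists, camera called 16, and 0 with an estimated correlation. In a 2-group fit, which called 15 lists for the real groups, other splits of the 8 libraries into 3 and 5 called up to 18.

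**Figure D4:**
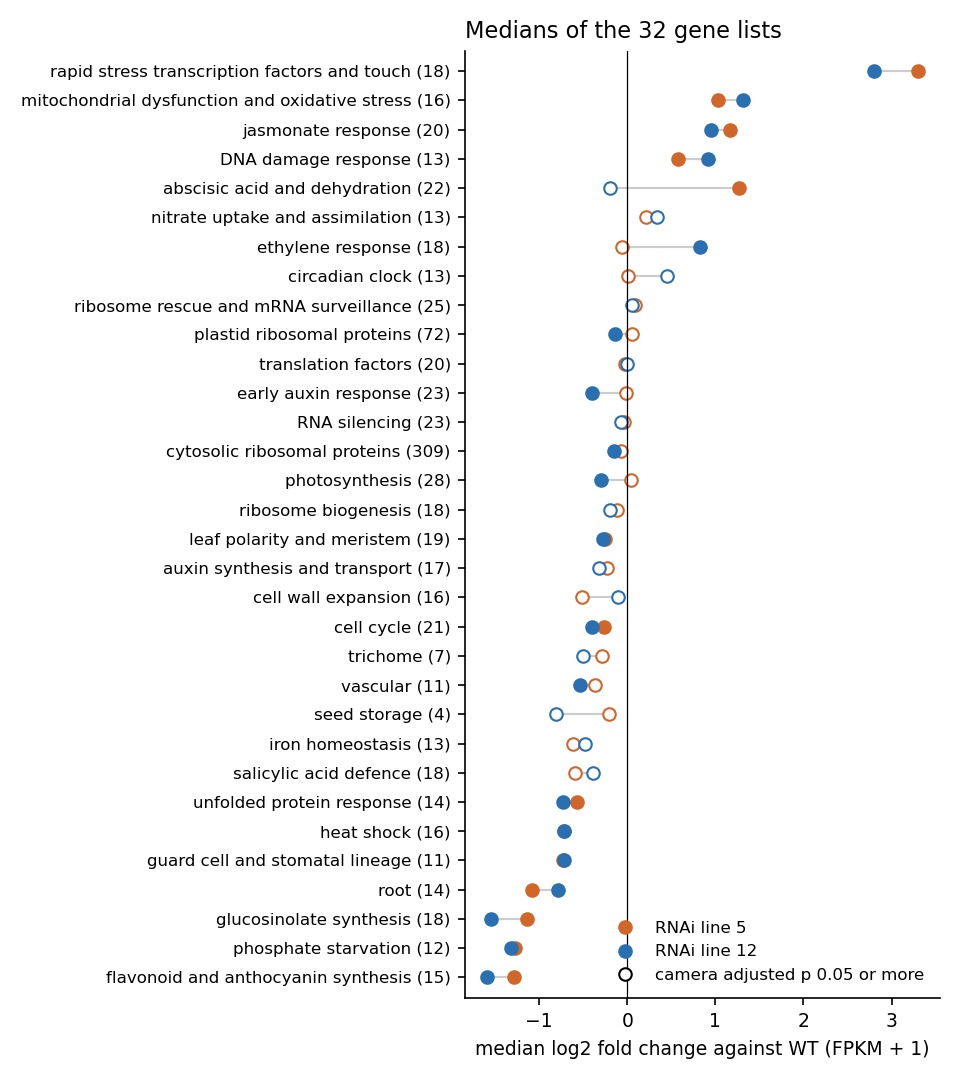
Median log2 fold change against WT (horizontal axis) of the 32 gene lists, with the number of measured genes in brackets, for line 5 and line 12. Filled points were called by camera with its preset correlation; the stress and touch list has the highest median in both lines, and the abscisic acid list at 1.27 in line 5 and -0.20 in line 12.

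The lines were also compared with each other, as line 12 less line 5, to ask whether they differ. The abscisic acid and dehydration genes were higher in line 5 than in line 12: 18 of 22 differed, all in that direction (19 adjusted over the list alone, median -1.15, camera adjusted p = 6.32e-12, and adjusted p = 0.546 with an estimated correlation). NCED3, the enzyme that limits abscisic acid synthesis, stood at 39.4 ± 3.11 FPKM in line 5 and 2.75 ± 0.890 in line 12 (difference -3.46, SE 0.193, adjusted p = 0.000136), against 3.42 ± 0.465 in WT. ERD10, COR47 and RD26 rose in both lines but differed by -1.98, -1.16 and -1.41. In the mean of the lines 10 of the 22 rose and 4 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.0436, and adjusted p = 0.755 with an estimated correlation), a call lost without WT replicate 3 (adjusted p = 0.144), line 5 replicate 2 (0.056), line 12 replicate 1 (0.0563) or line 12 replicate 3 (0.0573). This call also ended with a filter at 5 FPKM (adjusted p = 0.104) or a pseudocount of 0.1 (0.054). PUB19, a ubiquitin ligase, differed by -4.17, THI2.2 by -3.32, the phosphatase gene HAI1 by -3.17 and GolS2, a galactinol synthase, by -3.15.

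Higher in line 12 than in line 5 were EARLI1 (48.9 ± 1.96 FPKM in line 5, 624.4 ± 229.8 in line 12) and its neighbour AZI1 (93.5 ± 14.1 and 608.7 ± 177.6), lipid transfer-like proteins that resemble each other and may share reads, the glutathione transferase GSTU24 (2.33) and the nicotianamine synthase NAS3 (2.26). AT4G12490, of the same cluster, differed by 3.39 (adjusted p = 0.0304), a call lost without line 5 replicate 1 (2.65, adjusted p = 0.163), line 5 replicate 2 (4.13, 0.0686), line 12 replicate 2 (2.98, 0.0722) or line 12 replicate 3 (3.26, 0.083). The ethylene list was mostly higher in line 12, 10 of 18 members against 1 lower (10 and 3 adjusted over the list alone, median 0.72, camera adjusted p = 0.00081, and adjusted p = 0.546 with an estimated correlation). The lower member was ACS6 (-1.41, adjusted p = 0.000619), while ERF104 (-0.82, adjusted p = 0.0529) and ACS8 (-0.64, adjusted p = 0.095) missed the threshold over all genes. Genes annotated to ethylene signaling were enriched in both directions between the lines (Fisher's exact test). Of 138 such genes, 14 were among those at least 2-fold lower in line 12 (1.96 expected, adjusted p = 1.09e-06) and 10 among those at least 2-fold higher (2.4 expected, adjusted p = 0.0348). Photosynthesis genes were lower in line 12, 12 of 28 (21 adjusted over the list alone, median -0.30, camera adjusted p = 2e-07, and adjusted p = 0.57 with an estimated correlation), as were early auxin genes, 11 of 23 (12 adjusted over the list alone, median -0.46, camera adjusted p = 0.000323, and adjusted p = 0.57 with an estimated correlation). PRR5 and LHY differed in the same comparison, as given above, and 2 of the 3 line 12 libraries and 1 of the 2 line 5 libraries were above 2% ribosomal RNA. In all 3685 of 19395 genes differed, 1760 higher and 1925 lower in line 12, with 564 at least 2-fold. Camera called 11 of 32 lists, and 0 with an estimated correlation. The count was 2063 without line 5 replicate 1, 1403 without line 5 replicate 2 and 2288 without line 12 replicate 3, and 1539 with the replicate number as a block. Without the 3 libraries above 2% ribosomal RNA, which leaves 1 library per line, it was 431, and the calls of GolS2 (-2.95, adjusted p = 0.0932) and NAS3 (1.75, adjusted p = 0.139) ended.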

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

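The tests of harvest time, handling, clock genes and ABCE2 level in this part were chosen only after the results were seen, as were the enrichment tests, leaving out the libraries rich in ribosomal RNA and rescaling without ribosomal RNA and organelle genes. Results were listed here because the difference between the lines passed its own test. All 11 list differences passed with the preset correlation of camera, and 0 of them with an estimated correlation (adjusted p = 0.546 to 0.673).

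The lines differed in 3685 genes. The abscisic acid list differed by a median of -1.145 (line 12 less line 5), early auxin by -0.456, glucosinolate by -0.46, photosynthesis by -0.295 and rapid stress by -0.743. Ethylene differed by 0.719, but its member ACS6 differed by -1.41, and genes annotated to ethylene signaling were enriched among genes at least 2-fold lower in line 12 (14 of 138, Fisher's exact test, adjusted p = 1.09e-06) as well as higher (10, adjusted p = 0.0348). The clock list differed by 0.334, a call lost without line 5 replicate 1 (0.38, adjusted p = 0.0824) or with a filter at 5 FPKM (0.25, 0.0736). Plastid ribosomal proteins differed by -0.182, lost without line 5 replicate 2 (-0.13, adjusted p = 0.0528). Jasmonate differed by -0.277, lost without line 5 replicate 2 (-0.10, adjusted p = 0.254) or line 12 replicate 2 (-0.10, adjusted p = 0.0617), with the same filter (-0.28, adjusted p = 0.0712), and without the 3 libraries rich in ribosomal RNA (-0.03, adjusted p = 0.531). DNA damage differed by 0.323, lost without WT replicate 2 (0.32, adjusted p = 0.0508), line 5 replicate 2 (0.16, 0.256), line 12 replicate 2 (0.20, 0.144) or line 12 replicate 3 (0.21, 0.133). That call was also lost with the same filter (0.36, adjusted p = 0.231), the replicate block (0.23, 0.0789), a pseudocount of 0.1 (0.34, 0.0677) or rescaling (0.35, 0.0517), and the value turned to -0.01 (adjusted p = 0.976) without the 3 libraries rich in ribosomal RNA. The mitochondrial list differed by 0.394, lost without the 3 libraries rich in ribosomal RNA (-0.02, adjusted p = 0.528). Single genes were EARLI1 at 3.57, AT4G12490 at 3.39, AZI1 at 2.65, GSTU24 at 2.33, NAS3 at 2.26, PUB19 at -4.17, NCED3 at -3.46, THI2.2 at -3.32, HAI1 at -3.17 and GolS2 at -3.15. The AT4G12490 call ended in 4 of the leave-one-out fits, with values from 2.65 to 4.13 (without line 5 replicate 1 or 2, or line 12 replicate 2 or 3).

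The first pattern weighed is the rise of rapid stress and touch genes in both lines. A gap between library medians was argued against as its source. Median centring moved no library median by over 0.032 on the log2 scale and left the list's median at 3.22. Centring assumes that the median gene did not change, so scaling of another kind was not tested by it. Handling of whole groups before harvest and a response to the knockdown cannot be told apart, because the list's median was above every WT library in 5 of 5 RNAi libraries and both would give that. Another time of harvest may contribute: evening clock genes lay 1.79 above morning ones in the mean of the lines, but in line 5 the evening median (0.27) was small, and the stress genes differed between the lines by -0.74, the other way from the clock change. Genes annotated to the response to absence of light were enriched among genes at least 2-fold higher in both lines. They were 7 of 34 (1.28 expected, Fisher's exact test, adjusted p = 0.00661), and whether light or hour at harvest lies behind this was not tested. The design gives no harvest times, so another time of harvest stays open, as does a biological effect of less ABCE2.

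The second pattern is that over 50% of tested genes passed in line 12 and in the mean of the lines. Median centring gave 10996 calls, but it moved no library median by over 0.032 on the log2 scale, so a large drop could hardly arise. It also assumes that the median gene did not change, so it does not decide whether scaling is a cause. Dilution by ribosomal RNA was argued against by 10649 calls after rescaling without it and without organelle genes. Without the 3 libraries rich in it, 7012 of 19016 genes passed in line 12 and 8833 in the mean, both under 50%, in a fit with fewer libraries and 1 of each line, so another property of those libraries stays open. With 5 RNAi libraries as 1 group, the real split gave 9074 genes and the highest other split of 56 gave 2481. Thus 1 of 56 splits reached the real value, the smallest share possible. Most other splits mix the groups, which widens their spread and leaves few calls, while the split with 2481 kept line 12 whole. The real split gave the most calls, but this comparison does not exclude chance. For line 12 the real split gave 10589 and the highest other 1, with 1 of 10 splits as large, too few for a share under 0.05. For the number of called lists chance cannot be excluded in the mean of the lines, where 9 of 56 splits called as many (real 15, highest other 18, line 12 against the rest); for line 12 it was 1 of 10 (real 21, highest other 14), again too few splits.

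The third pattern is the higher level of abscisic acid genes in line 5 than in line 12. The measured ABCE2 level differed between the lines by -0.014 (95% interval -0.17 to 0.15). This argues against less ABCE2 transcript in 1 line only if reads from the RNAi construct did not add to it. That could not be checked here. A single library was argued against, since the list's median difference stayed at -1.1 or below with each RNAi library left out. A difference between the lines in insertion site, growth or handling was not tested and stays open.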

How the results depend on the processing

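Leaving out the 3 libraries rich in ribosomal RNA and rescaling were chosen only after the results were seen; the other alternatives were planned. ABCE2 kept its direction and call in every alternative run (line 5 -1.11 to -1.19, line 12 -1.09 to -1.20). Leaving out each library gave 5455 to 8800 genes in line 5, 9376 to 10579 in line 12, 9113 to 10716 in the mean, 4611 to 6570 in both lines and 1403 to 3607 between the lines; fits with 1 line 5 library assume that it varies like the others. A fold of at least 2 left 1835, 2152, 1851, 1238 (both lines) and 564 (between the lines), by construction. Without the 3 libraries rich in ribosomal RNA, 7012 genes passed in line 12 and 431 between the lines, with 1 library per line and the spread taken from WT alone; the DNA damage difference turned to -0.01 (0.32 with all libraries; adjusted p = 0.976), and the cause was not tested. The replicate block gave 1539 genes between the lines and moved no other count of genes by over 1.5 times; same-numbered libraries did not deviate together (7 pairs, r from -0.30 to 0.16, 1 above 0.1), so the numbers do not pair them. Lists called in line 5 were 9 of 31 with the filter at 5 FPKM (14 of 32 in the fit as reported), where fewer genes were tested (14489), and with an estimated correlation 0 lists were called in each of the 4 contrasts (14, 19, 16 and 11 with the preset one; lowest adjusted p = 0.546). Of 128 list results 60 were called; 52 of these stayed called in every leave-one-out fit and 41 in every other alternative, the estimated correlation aside. Of 168 named gene results 167 were called, which follows largely from the naming rule, since most of its parts took only called genes. Of these, 157 stayed called in every leave-one-out fit. Count-based tests, transcripts summed to genes and a comparison of FPKM with a count model were not run, since no counts or transcripts were analysed. Median centring moved no library median by over 0.032 on the log2 scale, but the share of calls that were higher went from 50.5% to 44.5% in line 12 and from 50.0% to 43.6% in the mean, against 55.6% and 54.0% after rescaling. Genes below the filter at 1 FPKM were tested only in the alternative with no filter (26269 genes). Whether depth (42280000 to 49010000 fragments) limits them was not tested.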

Other observations

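The enrichment tests and the genes in the first paragraph were chosen only after the results were seen; the tests of upstream ATGs and coding length were fixed before theirs.

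Genes at least 2-fold higher in both lines held 55 of 110 genes annotated to the response to chitin (4.15 expected; Fisher's exact test, one-sided, adjusted p = 2.4e-46) and 29 of 168 for wounding (adjusted p = 9.34e-10). Genes at least 2-fold lower in both lines held 19 of 93 for karrikin, a smoke compound (adjusted p = 6.53e-09), and 11 of 63 for UV-B (adjusted p = 0.000296). DIN10, a gene induced by darkness and low sugar, rose from 61.1 ± 13.98 FPKM to 106.1 ± 11.5 in line 5 and 305.2 ± 35.6 in line 12 (log2 0.80 and 2.32; limma adjusted p = 0.00796 and 1.88e-05). EXL2, an EXORDIUM-like gene, rose from 43.8 ± 0.384 to 199.4 ± 7.89 and 198.4 ± 5.26 FPKM. Beside MS2, the methionine cycle gene SAM1, an S-adenosylmethionine synthetase, changed by -1.08 and -1.24. Genes at least 2-fold lower in line 12 than in line 5 held 24 of 257 for water deprivation (adjusted p = 1.42e-10).

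A hypothesis was that transcripts with an ATG in the 5' untranslated region may rise when a recycling factor is reduced. The median change of 11358 genes with such an ATG differed from that of 6699 without by 0.005 in the mean of the lines (camera adjusted p = 0.967). This argues against a shift of 0.1 or more between these classes. Each gene was classed by its annotated transcript with the longest coding sequence, whether or not that one was expressed, and any ATG counted. A shift limited to some of these ATGs could be missed. A second hypothesis was that long coding sequences may fall; the 4648 genes with a coding length over 1686 bases differed from the other 13977 by -0.032 (camera adjusted p = 0.967), which argues against it in the same way.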
